A study of Homo sapiens with 12 samples.

How the data were processed

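The series measured primary human keratinocytes, the main cell type of the epidermis, in culture. RNA sequencing covered 4 libraries of differentiated cells, 2 with a control siRNA and 2 with an siRNA against CASZ1, a zinc finger transcription factor. Chromatin immunoprecipitation with sequencing (ChIP-seq) covered 8 libraries, 2 each for the transcription factor p63 and for acetylation of lysine 27 of histone H3 (H3K27ac) in progenitor and in differentiated cells. Per the labels' protocols, progenitor cultures were kept below 60% confluency, and differentiation lasted 4 days at confluency with 1.2 mM calcium chloride. The siRNAs were delivered by electroporation, and chromatin was crosslinked with formaldehyde, per the labels' protocols. Libraries are named by group and by the letter A or B of their label. The labels do not say whether the libraries of a group came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

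RNA was poly(A) selected and prepared with a directional kit, per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore, STAR, Salmon and DESeq2 for RNA, and FastQC, Trim Galore, BWA and MACS2 for ChIP-seq, with genome hg38 for both. Their versions, the transcript annotation, the strand setting of the counting and the peak calling options are not given in the sources used here. Because that strand setting is not stated, antisense and overlapping genes could share reads, and so could near-identical family members such as the SPRR2 and LCE genes, DEFB103A with its copy DEFB103B, and the PSG genes. The first RNA table holds estimated counts per gene that the authors deposited for each library, which need not be whole. The second is the authors' deposited comparison table, with scaled counts per library (a signal, counts divided by a size factor), log2 fold changes of CASZ1 siRNA over control siRNA with standard errors, a Wald statistic (a score), and p-values raw and adjusted. Multiplying the deposited scaled counts by 1 factor per library gave whole numbers, within 0.01, for 100% of values, and these equalled the rounded estimated counts. The peak lists were deposited separately for each library. They give a position, a score, a fold (a linear ratio of enrichment), a −log10 p and a −log10 q per peak, all the authors' own values per the file layout. The lowest −log10 q in any deposited list was 3.00. The number of reads behind the peak lists is not known here, and whether an input library was used is not given in the sources used here.

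The estimated counts were rounded to whole numbers. The 4 totals were 17081338 and 11321597 reads for control siRNA A and B, and 15452623 and 10209433 for CASZ1 siRNA A and B. Of 26475 genes in the table, 8170 had no read, and 13096 passed edgeR's filterByExpr and were tested. Normalisation was by TMM. CPM are counts scaled to TMM-adjusted library sizes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust dispersions), with group as the single term and Benjamini-Hochberg adjustment at 0.05. Standard errors of its log2 fold changes were taken from the fold change and the F statistic. DESeq2 1.42.0 was the alternative. Where the CASZ1 siRNA group held no read of a gene, the fold is a lower bound computed from a floor of 3 counts over the group. With 1 to 3 reads it is a ratio with an exact conditional Poisson interval at 95%, which covers counting error only. Genes of the Y chromosome and XIST were left out of all output.

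Before the data were examined, 22 gene lists were fixed, 7 main and 15 others, the latter including markers of other cell types and signs of RNA quality. Each list with at least 3 tested members was tested with limma 3.58.1's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry. None of the list calls at the preset correlation held with the estimated correlation, and the same was true of the sets of genes near regions. With an estimated correlation camera uses the residual degrees of freedom, which are few with 2 libraries per group. Few lists could pass then, so this loss does not show that correlation between genes made the preset calls. The cornified envelope list had an estimated correlation of 0.032 and a camera p of 0.0164 before adjustment. Within each list, edgeR p-values were also adjusted over the list alone.

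The rule for named genes, also fixed before, took CASZ1, the 12 largest falls and 12 largest rises past the edgeR threshold with a mean of at least 2 CPM and both CASZ1 siRNA libraries on 1 side of both controls, and up to 4 members of each list with the smallest p. The first part named 0 genes, since edgeR called none, so the same rule was applied, after seeing the data, to the adjusted p of the authors' deposited table. By that adjusted p, 110 genes met its conditions, 106 lower and 4 higher, of which the 12 largest falls and all 4 rises are named. Clone-style, numbered antisense and similar names were left out. Other list members past the threshold over the list alone, and the levels of FLG, TP63, KRT1, KRT5 and KRT14, were named after their values were seen.

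Peaks on the 22 autosomes and X were used. For each factor, peaks of the 4 libraries that shared at least 1 base were merged into regions. A region was called progenitor-only when both progenitor libraries and neither differentiated library had a peak in it, differentiated-only in the opposite case, and shared when all 4 libraries had one. The presence of a peak does not measure its height, so a region missing from a list can still hold signal under the calling threshold. Regions were assigned to the nearest protein-coding gene within 50 kb of the region's midpoint, with coordinates of the RefSeq annotation of GRCh38.p14, which has the same coordinates as hg38. Transcription starts had been planned for this, but the annotation used here gives no strand, so distances were taken to the gene's span and are 0 inside it. Of the 14328 genes near regions, 13984 matched a gene of the expression table. At 30 loci fixed beforehand, and for the 6 regions of each class with the best of the worse within-list percentile of the authors' fold, single regions are given. Overlaps between p63 and H3K27ac used regions with a peak in both libraries of a state and at least 1 shared base. Their background was the same p63 regions moved by 20 kb to either side, added after seeing the data. Two-sided Fisher's exact tests compare regions or genes, which are not independent replicates. A planned search for the p63 motif was not run, since no genome sequence was used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the regions.

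The steps were tested on simulated data. For 13096 simulated genes with the dispersions of the real libraries, edgeR called 21% of 100 genes changed 4-fold and 91% of 100 genes changed 16-fold with 5 false calls, and DESeq2 called 45% and 99% with 47 false calls. In the same simulation camera called a list that had been moved, and 0 of 20 unmoved lists. The simulated genes varied independently, so this does not test the preset correlation on lists whose genes vary together. Nor did the simulation hold a difference shared by libraries of the same letter. In the real data edgeR called 0 genes, with CDSN at a log2 difference of −4.00 and ASPRV1 at −6.16 among those uncalled. The simulated percents therefore do not carry over to these libraries, and 0 edgeR calls do not show that such changes are absent. The alternatives covered normalisation, filters, tool, a term for the library letter, leaving out each library, peak thresholds, numbers of peaks, overlap rules and distances to genes. Each group has 2 libraries, so rules that look for a single outlying sample among 4 or more could not be applied.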

Results

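RNA sequencing compared differentiated human keratinocytes given a control siRNA with cells given an siRNA against CASZ1, a zinc finger transcription factor, in 2 libraries per group. The comparison asks which transcripts depend on CASZ1 in cells that have begun to differentiate. The libraries held 17081338 and 11321597 estimated reads for control siRNA A and B, and 15452623 and 10209433 for CASZ1 siRNA A and B. ChIP-seq of p63, the transcription factor that maintains the epidermal lineage, and of H3K27ac, a histone mark of active enhancers and promoters, compared progenitor with differentiated keratinocytes, in 2 libraries per group. The p63 peak lists held 19513 and 30044 peaks in progenitor A and B, and 16318 and 17313 in differentiated A and B. Those of H3K27ac held 76411 and 82458 peaks in progenitor A and B, and 67400 and 66261 in differentiated A and B. The read depth behind the peaks is unknown.

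CASZ1, the siRNA's target, was at 56.5 and 30.7 CPM (counts scaled to library size) in the control libraries and at 3.8 and 2.61 CPM in the CASZ1 siRNA libraries. The log2 difference was −3.76 (SE 0.56, n = 2 per group), lower in both siRNA libraries than in both controls, with an adjusted p of 0.395 by edgeR. In the authors' deposited table, made with DESeq2, CASZ1 fell by a log2 fold change of −3.72 (SE 0.61) with an adjusted p of 7.3e-07. DESeq2 run here gave −3.22 without control A, −4.10 without control B, −4.04 without CASZ1 siRNA A and −3.48 without CASZ1 siRNA B. The call ended without control A and held in the other fits.

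LCE3D, a late cornified envelope gene, was at 2649 and 595 CPM in the control libraries and at 7.68 and 13 CPM with CASZ1 siRNA, a fall of −7.26 on the log2 scale in the authors' deposited table (DESeq2 adjusted p 6.5e-22). LCE1A, of the same family, was at 664 and 46 CPM and then at 0.211 and 0.180 CPM, with −10.77 in the authors' deposited table. SMPD3, a neutral sphingomyelinase, was at 76.0 and 4.62 CPM and then at 0.0704 and 0.270 CPM, with −7.91 in that deposited table of the authors. DEFB103A, which encodes an antimicrobial beta-defensin, was at 139 and 54.7 CPM in the controls and had 0 reads with CASZ1 siRNA, at least 819-fold lower. KCTD4, at 49.5 and 5.76 CPM in the controls, also had 0 reads with CASZ1 siRNA and was at least 233-fold lower, a bound that rests mostly on control A. For genes with 1 to 3 reads in the siRNA group, the ratio of control to CASZ1 siRNA was 299 for the claudin CLDN17 (95% counting interval 53.2 to 11832), 326 for LCE6A (89.8 to 2693) and 184 for LCE1D (62.5 to 893). For LCAL1 it was 348 (62.1 to 13775), for PSG2 165 (56.3 to 805) and for PSG7 3615 (649 to 142838). These ratios rest mostly on control A. Control A and B stood at 238 and 3.23 CPM for PSG7, 22.5 and 0.959 CPM for LCAL1, 31.0 and 2.97 CPM for PSG2, 35.2 and 2.09 CPM for LCE1D, 38.7 and 6.72 CPM for LCE6A, and 16.9 and 4.27 CPM for CLDN17. LCE1B was at 211 and 5.76 CPM, and at 0.563 and 0.180 CPM with CASZ1 siRNA. The LCE and PSG genes and DEFB103A have near-identical relatives, so how reads were shared among those is uncertain.

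Among the genes that rose, SPRR2A, a small proline-rich envelope precursor, was at 13.7 and 23.3 CPM in the controls and at 148 and 119 CPM with CASZ1 siRNA (log2 fold change 2.89 and DESeq2 adjusted p 6.2e-05 in the authors' deposited table). SPRR3, of the same class, went from 286 and 326 CPM to 1041 and 1239 CPM (1.93, DESeq2 adjusted p 0.0168 in the authors' deposited table). The cytokine gene IL1B was at 59.1 and 76.8 CPM and then at 503 and 225 CPM (2.46, DESeq2 adjusted p 0.0041 in the authors' deposited table). LCP1, an actin-bundling protein, was at 14.0 and 16.4 CPM and then at 141 and 58.4 CPM (2.75, DESeq2 adjusted p 0.0011 in the authors' deposited table).

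The authors' deposited table called 117 genes lower and 7 higher, and DESeq2 run here called the same 124 genes. The edgeR quasi-likelihood test called 0 of 13096 genes, with a smallest adjusted p of 0.298. At an unadjusted p under 0.05 edgeR gave 513 lower and 45 higher genes, 558 in all. Chance gives 655 over both directions together, so the total does not reflect the uneven split toward lower genes. Genes vary together, so that split is not a test. All 119 of the called genes in the edgeR test were among the 558. The count of DESeq2 was 22 lower and 4 higher genes without control A, 192 and 21 without control B, 73 and 4 without CASZ1 siRNA A, and 119 and 19 without CASZ1 siRNA B. By edgeR the counts without those libraries were 6 and 2, 96 and 3, 4 and 0, and 18 and 7. The groups did not overlap in 4230 genes, 2243 lower and 1987 higher, where chance gives 4365.

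**Figure D1:**
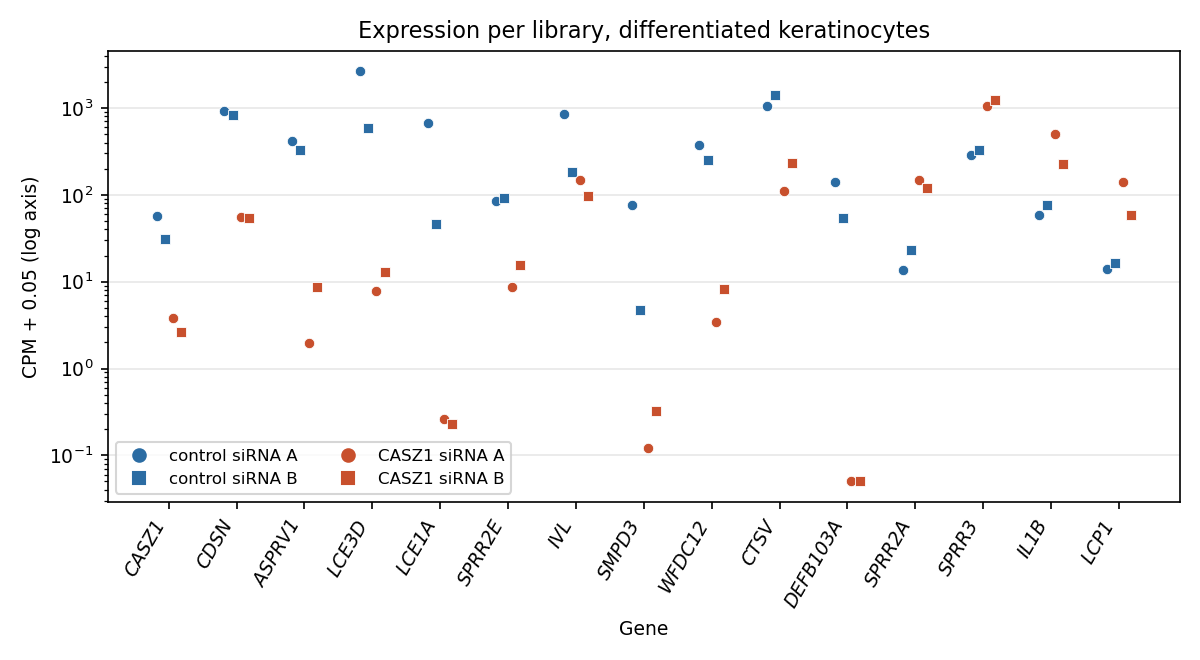
Levels of 15 genes in CPM plus 0.05 on a log axis, with a point for each of the 2 control siRNA and 2 CASZ1 siRNA libraries. CASZ1 lies at 56.5 and 30.7 CPM in the controls and at 3.8 and 2.61 CPM with CASZ1 siRNA, and SPRR2A at 13.7 and 23.3 CPM and then at 148 and 119 CPM.

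Cornified envelope genes, which encode the proteins and cross-linkers of the dead outer cell layers, had a median log2 difference of −2.33 over 46 tested members, also with the 3 members without reads in the siRNA group set at their bound. CDSN, an adhesion protein of the cornified layer, was at 918 and 823 CPM in the controls and at 55.6 and 53.3 CPM with CASZ1 siRNA, a log2 difference of −4.0 (SE 0.39). ASPRV1, a protease that processes filaggrin, was at 421 and 330.0 CPM and then at 1.90 and 8.65 CPM. IVL, which encodes involucrin, was at 853 and 184 CPM and then at 147 and 98.0 CPM. CRCT1 was at 2953 and 1203 CPM and then at 343 and 185 CPM. By edgeR, 27 members fell and 2 rose, SPRR2A and SPRR3, adjusted over the list alone, while over all genes 0 passed in edgeR, with 30 lower and 2 higher at an unadjusted p under 0.05, and 19 lower and 2 higher passed in the authors' deposited table. Limma voom, added after seeing the data, called 15 lower and 2 higher adjusted over the list alone. Adjusted over the list alone, the LCE1 genes fell in 6 of 6 tested members, the LCE2 genes in 2 of 2 and the LCE3 genes in 4 of 4, and of 5 SPRR2 genes 4 fell and 1 rose. LCE2B, LCE2C and LCE3C had 0 reads with CASZ1 siRNA and were at least 372-fold, 341-fold and 98.0-fold lower than the mean of the controls. These bounds come mostly from control A, where the genes were at 86.7, 79.3 and 22.5 CPM, against 1.57, 1.66 and 0.785 CPM in control B. The log2 differences of SPRR1A, SPRR1B, CSTA and SCEL were −0.11, −0.43, −0.28 and −0.32 and passed no test in the main edgeR fit or the authors' deposited table. FLG, which encodes filaggrin, was at 32.0 and 209 CPM and then at 2.04 and 20.4 CPM, with an edgeR p of 0.052 adjusted over the list alone and a DESeq2 adjusted p of 0.025 in the authors' deposited table. Limma camera gave an adjusted p of 5.0e-22 for the list with its preset correlation, and an adjusted p of 0.312 with an estimated correlation. Without control A 21 members fell adjusted over the list alone, without control B 28, without CASZ1 siRNA A 12 and without CASZ1 siRNA B 13.

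Genes of the epidermal lipid barrier had a median log2 difference of −1.08 over 35 tested members. SDR9C7, a dehydrogenase of acylceramide processing, was at 51.4 and 46.6 CPM in the controls and at 10.1 and 6.04 CPM with CASZ1 siRNA (log2 difference −2.60, SE 0.47). TMEM86A was at 135 and 52.4 CPM and then at 4.93 and 6.58 CPM (−4.03, SE 0.62), and ELOVL4, which elongates very long chain fatty acids, at 297 and 221 CPM and then at 86.8 and 58.7 CPM. By edgeR 5 members fell and 0 rose adjusted over the list alone, namely these 3 with SMPD3 and ABHD12B, whose ratio of control to CASZ1 siRNA was 41.6 (95% counting interval 11.2 to 348). Over all genes edgeR called 0, with 16 lower and 1 higher at an unadjusted p under 0.05, and 4 were lower in the authors' deposited table, or 11 lower and 1 higher adjusted over the list alone. For this list limma camera gave an adjusted p of 3.1e-11 with the preset correlation, and an adjusted p of 0.318 with an estimated correlation. Adjusted over the list alone, 3 members fell without control A, 2 without CASZ1 siRNA A and 2 without CASZ1 siRNA B.

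Proteases of the upper epidermis and their inhibitors had a median log2 difference of −0.95 over 36 tested members. WFDC12, of a family of protease inhibitors, was at 372 and 254 CPM in the controls and at 3.38 and 8.29 CPM with CASZ1 siRNA (log2 difference −5.75, SE 0.66). CST6, a cysteine protease inhibitor, was at 284 and 294 CPM and then at 24.6 and 45.9 CPM, and CTSV, a cysteine protease, at 1064 and 1410.4 CPM and then at 111 and 230 CPM. KLK5, a kallikrein of corneocyte shedding, was at 2514 and 2725 CPM and then at 935 and 1110.0 CPM. By edgeR 9 members fell and 0 rose adjusted over the list alone, these 4 with WFDC5, SLPI, TMPRSS13, PI3 and KLK6. Over all genes edgeR called 0, with 13 lower and 0 higher at an unadjusted p under 0.05, and 6 were lower in the authors' deposited table. Limma camera gave an adjusted p of 5.6e-18 with the preset correlation, and an adjusted p of 0.489 with an estimated correlation. Without control B 5 members fell adjusted over the list alone.

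Spinous layer genes, of early differentiation, had a median log2 difference of −0.27 over 31 tested members. LYPD5 was at 191 and 312 CPM in the controls and at 26.1 and 43.7 CPM with CASZ1 siRNA (log2 difference −2.85, SE 0.51). It was the 1 member that fell adjusted over the list alone by edgeR and the 1 called in the authors' deposited table, while edgeR over all genes called 0, with 6 lower and 0 higher at an unadjusted p under 0.05. DMKN, PKP1 and SBSN had log2 differences of −1.22, −1.37 and −1.23 and passed no adjusted test in the main edgeR fit or the authors' deposited table. As a set, the list had a limma camera adjusted p of 0.0036 with the preset correlation, and an adjusted p of 0.489 with an estimated correlation. The preset camera call of limma ended without control B (adjusted p 0.635) and without CASZ1 siRNA B (0.357), and adjusted over the list alone by edgeR 2 members fell without control A, 0 without control B or CASZ1 siRNA A, and 1 fell and 2 rose without CASZ1 siRNA B. KRT1, a spinous keratin, varied within groups, at 14.5 and 187 CPM in the controls and 17.6 and 26.1 CPM with CASZ1 siRNA.

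Transcription factors of epidermal differentiation had a median log2 difference of −0.25 over 37 tested members. HOPX, PPARD and PRDM1 had log2 differences of −1.44 (SE 0.33), −1.70 (SE 0.40) and −1.59 (SE 0.39), and DLX3 −1.74 (SE 0.62). By edgeR 0 members passed over all genes or adjusted over the list alone, with 5 lower and 0 higher at an unadjusted p under 0.05. The authors' deposited table called 0 over all genes and 2 lower adjusted over the list alone. In limma camera the list had an adjusted p of 0.0057 with the preset correlation, and an adjusted p of 0.489 with an estimated correlation. Without CASZ1 siRNA B the preset test of limma camera turned to higher, with an adjusted p of 0.987. TP63 itself was at 110 and 111 CPM in the controls and at 112 and 125 CPM with CASZ1 siRNA.

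Basal layer genes, among them integrins and hemidesmosome proteins, had a median log2 difference of −0.32 over 46 tested members. IGFBP6 and S100A2 had log2 differences of 1.63 (SE 0.46) and 0.95 (SE 0.34), and ITGB4 and LAMB3, of the hemidesmosome and its basement membrane anchor, −1.22 (SE 0.47) and −1.34 (SE 0.52). By edgeR 0 passed over all genes or adjusted over the list alone, with 2 lower and 2 higher at an unadjusted p under 0.05, and 0 in the authors' deposited table. Without CASZ1 siRNA B, 8 members fell and 1 rose by edgeR adjusted over the list alone. Limma camera gave an adjusted p of 0.134 with the preset correlation and an adjusted p of 0.489 with an estimated correlation. Cell cycle genes had a median log2 difference of 0.52 over 50 members, with 0 past edgeR over all genes or adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 in the authors' deposited table. Limma camera gave this list an adjusted p of 2.0e-04 with the preset correlation, and an adjusted p of 0.627 with an estimated correlation. The preset call of limma camera ended without control B (adjusted p 0.670) and turned to lower without CASZ1 siRNA A (0.793). Library A exceeded library B within each group by a larger median, 1.11 in the controls and 1.35 with CASZ1 siRNA.

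**Figure D2:**
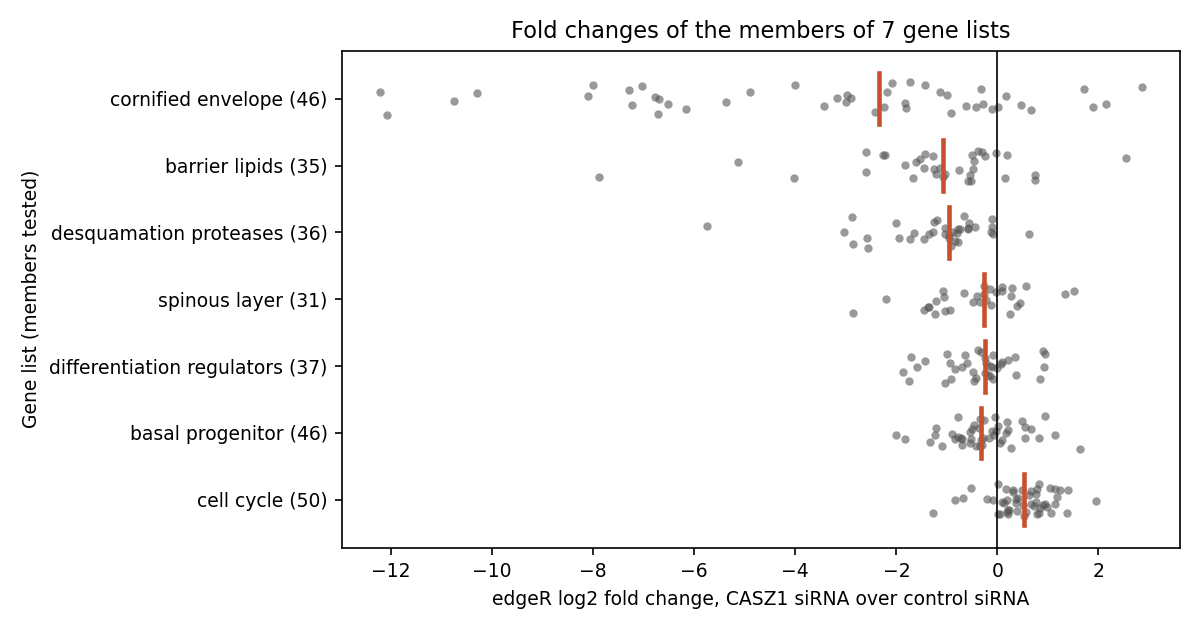
Log2 differences, CASZ1 siRNA minus control siRNA, of the tested members of the 7 main gene lists, a point per gene, with the list medians. The medians run from −2.33 for cornified envelope genes to 0.52 for cell cycle genes.

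Binding of p63 was compared between progenitor and differentiated keratinocytes. Of 31600 merged regions, 12665 had a peak in all 4 libraries, 4589 in both progenitor libraries alone and 599 in both differentiated libraries alone. The progenitor-only regions that ranked highest by the authors' fold included one on chromosome 3 (195030900 to 195031628, hg38), 37020 bases from XXYLT1, and one on chromosome 6 (43733891 to 43734534), 35998 bases from VEGFA, which encodes an angiogenic growth factor. Others lay inside the spans of FUCA1 (chromosome 1, 23865520 to 23865903) and of the kinase gene MAP2K2 (chromosome 19, 4104951 to 4105278). The differentiated-only region of highest rank was on chromosome 9 (86912128 to 86912347), 32124 bases from GAS1, followed by one on chromosome 8 (30358646 to 30358871), 25782 bases from RBPMS. Of the progenitor-only regions 55.4% lay inside a protein-coding gene's span, and of the differentiated-only regions 42.2%. No test was run on these counts. With the same number of peaks from every library they were 2049 progenitor-only and 1980 differentiated-only. Lists of equal length tend to bring these counts together by construction, so they do not show whether the number of binding sites differs. When a peak had to cover 50% of the region, 7232 were progenitor-only, 617 differentiated-only and 8749 shared. Without progenitor A the progenitor-only count was 12912, and the differentiated-only count was 2031 without progenitor B, 1071 without differentiated A and 1005 without differentiated B.

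For H3K27ac, 32059 of 104813 merged regions had a peak in all 4 libraries, 19377 in both progenitor libraries alone and 12601 in both differentiated libraries alone. The progenitor-only region of highest rank was on chromosome 17 (48481724 to 48483496), 37549 bases from SKAP1, followed by one inside DAP (chromosome 5, 10704692 to 10705833). The differentiated-only region of highest rank was on chromosome 6 (136968825 to 136970083), 30517 bases from IL20RA, which encodes a cytokine receptor subunit, followed by one on chromosome 2 (209382256 to 209384058), 40890 bases from MAP2. With the same number of peaks from every library, which tends to balance the counts by construction, 14596 regions were progenitor-only and 14218 differentiated-only. When a peak had to cover 50% of the region, 20019 were shared. Without progenitor A the progenitor-only count was 34192, and the differentiated-only count was 19820 without differentiated A and 19894 without differentiated B.

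**Figure D3:**
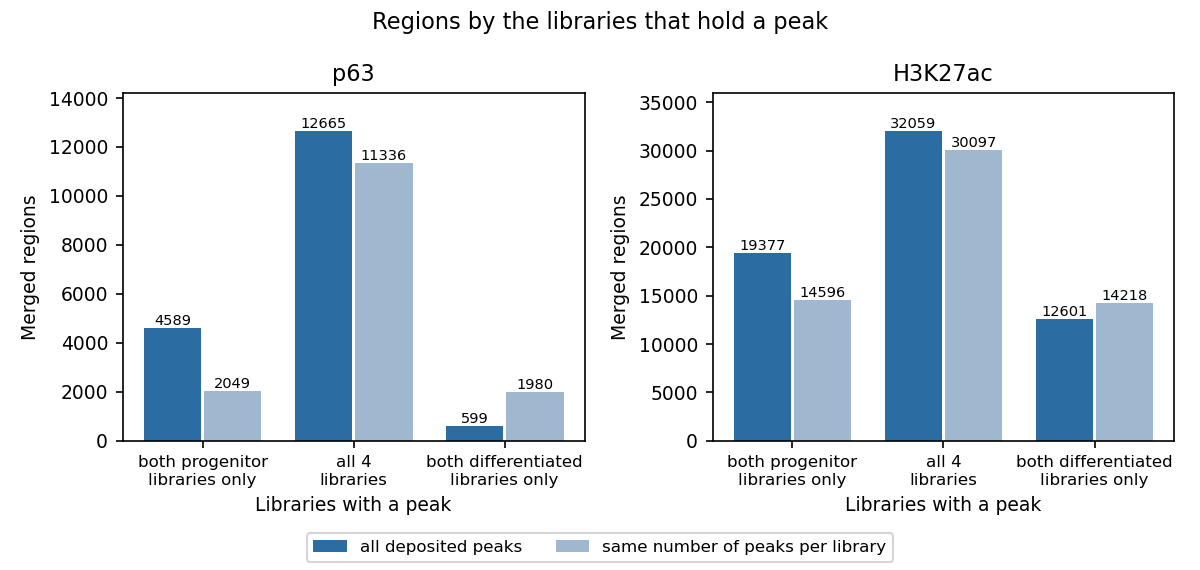
Numbers of merged p63 and H3K27ac regions with a peak in both progenitor libraries alone, in all 4 libraries, or in both differentiated libraries alone, from all deposited peaks and from the same number of peaks per library. For p63 the progenitor-only and differentiated-only bars are 4589 and 599 with all peaks, and 2049 and 1980 with equal numbers. Equal numbers tend to balance these bars by construction.

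There were 17 progenitor-only H3K27ac regions nearest to LAMB3, 12 nearest to COL17A1 and 11 nearest to ITGA6, which encode a laminin chain, a hemidesmosomal collagen and an integrin of the basal layer. Without progenitor A these counts were 32, 24 and 20, and without progenitor B 32, 22 and 18. Differentiated-only regions at LAMB3, COL17A1 and ITGA6 numbered 0, but 3, 1 and 7 with summits widened to 200 bases, and COL17A1 had 1 without differentiated B. There were 7 differentiated-only regions nearest to the keratin gene KRT1, 8 to the lipid transporter gene ABCA12, 6 to KLF4 and 6 to CEBPA, which encode transcription factors, with 0 progenitor-only regions at these 4 genes. The count was 12 at KRT1 without differentiated B and 11 at CEBPA without differentiated A, and ABCA12 had 1 progenitor-only region without progenitor B or with widened summits and KLF4 1 with widened summits. PRDM1 had 5 differentiated-only and 0 progenitor-only regions, but 10 differentiated-only and 1 progenitor-only without differentiated A, and 3 progenitor-only without progenitor A, 2 without progenitor B, 3 with widened summits and 2 when a peak had to cover 50% of the region. TP63 had 20 differentiated-only, 3 progenitor-only and 21 shared H3K27ac regions, with 33 differentiated-only without differentiated B, and 7 progenitor-only without progenitor B or with widened summits, 5 without differentiated A or with 50% coverage, and 1 with equal numbers of peaks. For KRT5 and KRT14, basal keratin genes, all 2 and 3 H3K27ac regions were shared, while with widened summits KRT5 had 2 and KRT14 1 of each state alone. KRT5 had 1 differentiated-only and 1 shared region with 50% coverage, and 1 shared region with equal numbers of peaks or without differentiated B. LCE3D had 2 regions, both differentiated-only, and FLG had 0 regions of either factor. No test was run on these counts of regions.

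**Figure D4:**
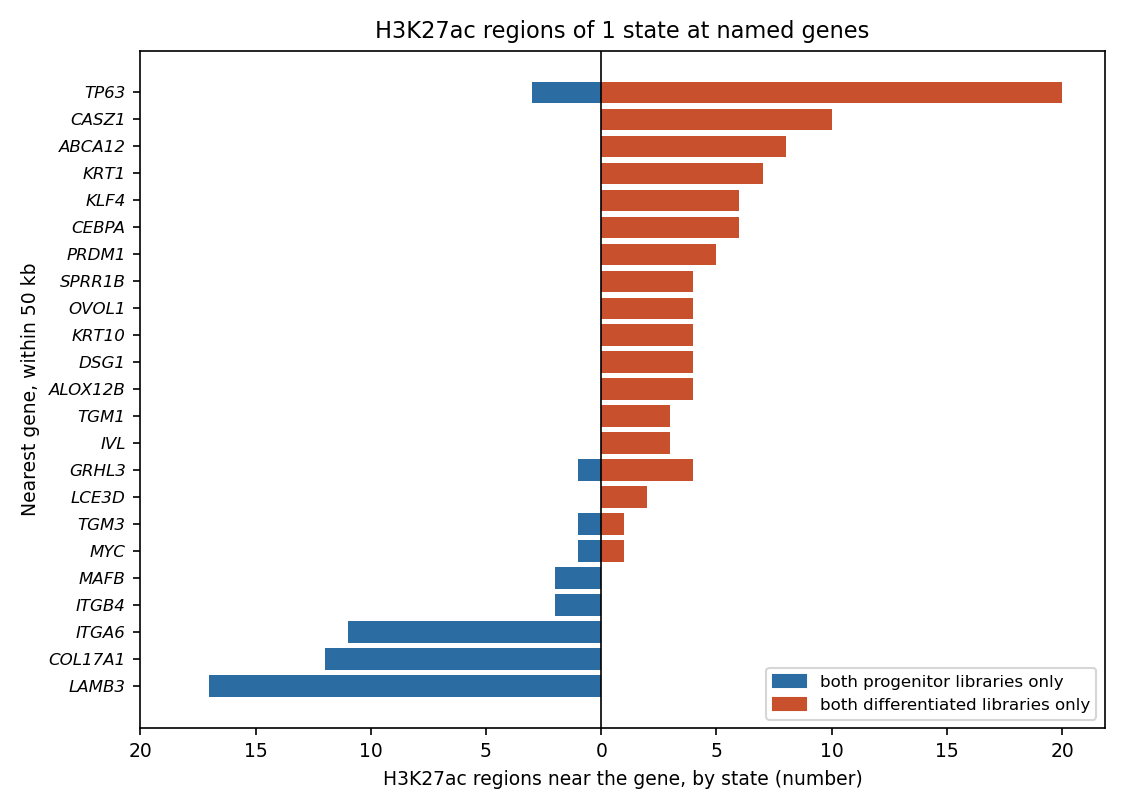
Numbers of H3K27ac regions with peaks in both progenitor libraries alone (left) or both differentiated libraries alone (right), by the nearest protein-coding gene within 50 kb, for loci fixed beforehand that had any. LAMB3 has 17 progenitor-only and 0 differentiated-only regions, and KRT1 0 and 7.

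CASZ1 spans 10636604 to 10796646 on chromosome 1. It was the nearest gene of 28 H3K27ac regions, of which 10 were differentiated-only, 5 shared and 0 progenitor-only. The differentiated-only count was 19 without differentiated B and 14 without differentiated A, and without progenitor A 1 region was progenitor-only. With 50% coverage 3 H3K27ac regions and 1 p63 region were shared. A differentiated-only region at 10794823 to 10796597 lies at the gene's upper end, and others lie within it, such as 10693678 to 10694342 and 10775383 to 10775848. Of 7 p63 regions, 2 were shared, at 10635234 to 10636452 and 10818665 to 10818984, and 3 were progenitor-only, at 10646465 to 10646690, 10765330 to 10765593 and 10824948 to 10825240. Without progenitor A, 5 p63 regions were progenitor-only. The differentiated-only count of p63 was 0, and 1 with summits widened to 200 bases.

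**Figure D5:**
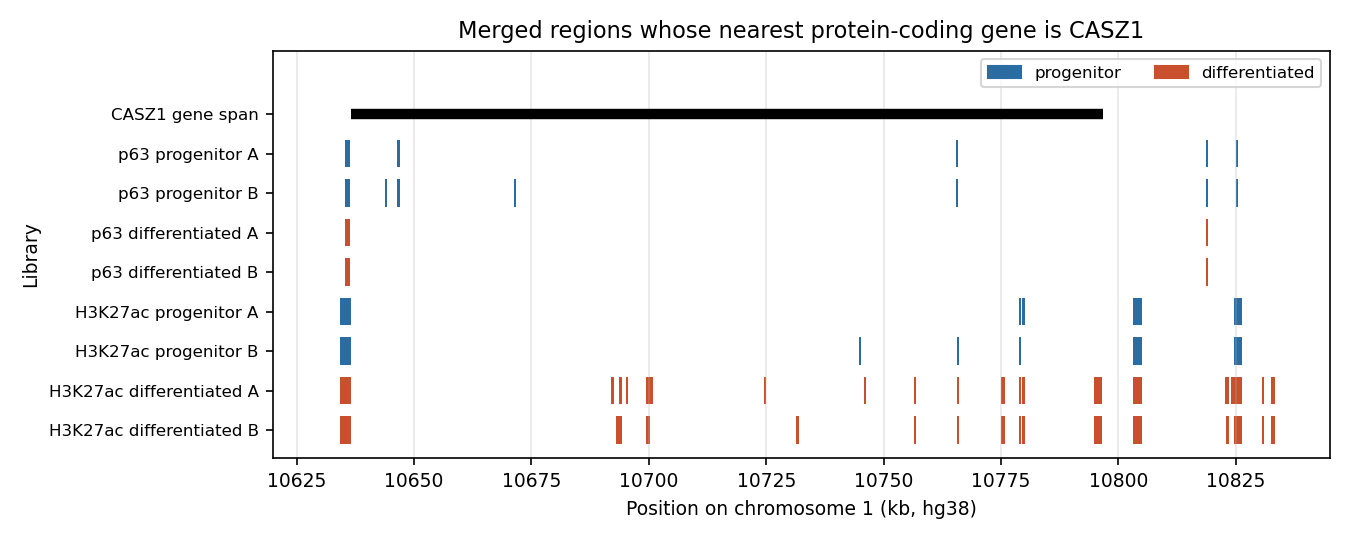
Merged regions at CASZ1 on chromosome 1 (hg38, position in kb), drawn for each of the 8 libraries that has a peak in them, with the gene's span as a bar. H3K27ac has 10 regions with a peak in both differentiated libraries alone and p63 has 3 with a peak in both progenitor libraries alone.

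Whether p63 sites carry H3K27ac was asked in each state. In progenitor cells 49.7% of 19162 p63 regions overlapped an H3K27ac region of the same state, and 42.9% one of differentiated cells. In differentiated cells 39.4% of 14807 p63 regions overlapped one of the same state, and 40.5% one of progenitor cells. This order turned with the same number of peaks from every library, at 39.4% and 37.98%, and with the p63 summit inside the H3K27ac region, at 20.5% and 18.2%. The same p63 regions moved by 20 kb to either side overlapped at 5.38% and 5.33% in progenitor and at 3.92% and 3.69% in differentiated cells. The same-state percents of progenitor and differentiated cells gave a p of 3.8e-79 by Fisher's exact test across regions (odds ratio 1.52). Shared p63 regions were counted in both states, so this p does not compare separate groups. The H3K27ac peaks also covered more of the genome in progenitor A and B, 41.4 and 45.6 megabases, against 38.3 and 36.8 in differentiated A and B. Of the 599 differentiated-only p63 regions, 72 (12%) overlapped differentiated-only H3K27ac regions, against 48 of 4589 progenitor-only ones (1.05%, Fisher's exact p 3.0e-38). Of the progenitor-only p63 regions, 586 (12.8%) overlapped progenitor-only H3K27ac regions, against 1 of the 599 (Fisher's exact p 6.6e-32) and 1266 of 12665 shared p63 regions (10.0%, odds ratio 1.32, Fisher's exact p 3.4e-07). Of the shared p63 regions 706 (5.57%) overlapped differentiated-only H3K27ac regions. Shared H3K27ac regions were overlapped by only 33 of the 599 differentiated-only p63 regions (5.51%). The counts were 1884 of 4589 for progenitor-only p63 regions (41.1%) and 5124 of 12665 for shared ones (40.5%). Regions are not independent replicates, and when the p63 summit had to lie inside the H3K27ac region the overlaps were 22% in progenitor and 20.5% in differentiated cells.

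The siRNA response was then compared between genes near each class of region and all other tested genes. The others could include genes with no region nearby and genes that are not protein-coding, to which no region could be assigned. A gene could be in several sets, so these comparisons do not contrast the classes with each other. Genes nearest to differentiated-only H3K27ac regions were called lower in the authors' deposited table more often than other genes, 57 of 3883 (1.47%) against 56 of 9213 (0.608%), with an odds ratio of 2.44 and an adjusted p of 1.8e-05 by Fisher's exact test. For genes nearest to progenitor-only H3K27ac regions the authors' deposited table called 31 of 5316 (0.583%) lower against 82 of 7780 others (1.05%), adjusted p 0.0096 by Fisher's exact test. For the 3 p63 sets the adjusted p of Fisher's exact test on these calls ran from 0.478 to 0.920. Counting genes lower at an unadjusted edgeR p under 0.05 instead, all 3 p63 sets passed Fisher's exact test, with 5.89% against 3.48% of others for progenitor-only regions (adjusted p 4.4e-07), 4.77% against 3.51% for shared regions (0.0011) and 7.03% against 3.86% for differentiated-only regions (0.018). On that count the differentiated-only H3K27ac set stood at 6.52% against 2.82% (Fisher's exact adjusted p 8.5e-21), and the progenitor-only H3K27ac set turned to 4.25% against 3.69%, with an adjusted p of 0.108 by Fisher's exact test. Both ways of counting lower genes were chosen after seeing the data. For genes higher at an unadjusted edgeR p under 0.05, 45 in all, no set passed Fisher's exact test, with a lowest adjusted p of 0.287. Without control A, DESeq2 called 11 of 3876 genes lower in the differentiated-only H3K27ac set (0.284%) and 11 of 9156 outside it (0.120%), an odds ratio of 2.37 with a p of 0.058 by Fisher's exact test, which ends the call on fewer called genes. The counts were 74 of 3836 against 103 of 8927 without control B (odds ratio 1.69, Fisher's exact p 0.00091), 38 of 3880 against 34 of 9195 without CASZ1 siRNA A (2.66, Fisher's exact p 4.4e-05) and 49 of 3882 against 67 of 9213 without CASZ1 siRNA B (1.74, Fisher's exact p 0.0040). Over all members, every set had a negative median log2 difference. It was −0.096 for genes near progenitor-only H3K27ac regions against 0.060 for others (limma camera adjusted p 0.062). Near shared p63 regions it was −0.091 against 0.040 (limma camera adjusted p 0.062), and near differentiated-only p63 regions −0.085 against 0.0030 (limma camera adjusted p 0.298). The preset test called the differentiated-only H3K27ac set, at −0.095 against 0.040 (limma camera adjusted p 0.032). It also called the progenitor-only p63 set, at −0.17 against 0.036 (limma camera adjusted p 0.014). With an estimated correlation limma camera gave both an adjusted p of 0.231. The preset call of limma camera ended for the H3K27ac set without control A (adjusted p 0.134), control B (0.0856) or CASZ1 siRNA B (0.914), and for the p63 set without control A (0.134) or CASZ1 siRNA B (0.465).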

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

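The tests on recovered whole reads, with limma voom, with DESeq2 without each library or with the block, of called genes near regions, and on p63 overlaps with equal numbers of peaks were chosen after seeing the data, as was naming genes by the authors' adjusted p. The other alternatives were fixed before, the comparison with the authors' deposited table among them. The count of genes past the threshold rests on the tool and on single libraries, and the cause was not tested. With no filter beyond a total above 0, edgeR gave CASZ1 −3.73 (adjusted p 2.0e-04) with 63 lower and 6 higher genes. DESeq2 and the authors' deposited table each gave −3.72, 117 and 7. Other normalisations, a stricter filter, recovered reads and voom each called 0 genes. Leaving out 1 library, edgeR's CASZ1 value ran from −4.06 to −3.23, lower genes from 4 to 96 and higher genes from 0 to 7. A lone library was then assumed to vary like the other group. By edgeR the replicate block (library letter) gave CASZ1 −3.73 (adjusted p 0.0022) with 111 lower and 5 higher genes. Of these 116, 74 were shared with the authors' calls. By DESeq2 the block gave CASZ1 −3.70 (adjusted p 1.2e-11) with 274 lower and 13 higher genes. Adjusted over the list alone by edgeR, the block gave 21 lower protease, 18 barrier, 8 spinous and 3 regulator genes, against 9, 5, 1 and 0 without it, 32 lower and 3 higher cornified genes against 27 and 2, and 3 lower and 3 higher wound genes against 2 and 1. It also gave 1 higher barrier and 1 higher basal gene, and 2 lower p53, 2 unfolded protein, 2 Notch, 1 histone and 1 fibroblast gene, against 0 in each without it. A minus B correlated at 0.484 between the groups across 13096 genes, which are not independent, and the component holding 51.0% of the variance parted the letters, but with 2 pairs and no shared donor or day in the labels the letters were not taken as a pairing.

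With an estimated correlation limma camera had few residual degrees of freedom, so few lists could pass. Its adjusted p was then 0.312 for cornified envelope, 0.318 for barrier lipids, 0.489 for spinous, protease and regulator lists and 0.627 for cell cycle. By fry of limma it was 0.248, 0.253, 0.387, 0.320, 0.499 and 0.897 for cornified, barrier, spinous, protease, regulator and cell cycle lists, and 0.897 with the opposite direction for p53 targets. Without 1 library, the adjusted p of preset limma camera ran from 1.2e-07 to 0.635 for spinous, 1.6e-06 to 0.987 for regulators, 3.8e-14 to 0.793 for cell cycle, 0.0426 to 0.992 for wound genes, 1.4e-11 to 0.0974 for cholesterol synthesis, 0.332 to 0.596 for mesenchymal matrix, 0.154 to 0.766 for p53 targets, 1.4e-05 to 0.865 for unfolded protein, 0.00026 to 0.369 for hypoxia and 0.00012 to 0.0287 for melanocyte genes. The last 9 of these 10 lists changed direction in at least 1 of those fits, and the cause was not tested. The log2 difference of KRT1 ran from −3.08 to 0.67, of KRT14 from −0.11 to 1.07 and of KRT5 from −0.12 to 0.96. The cornified, barrier and protease calls held in every such fit. Of the values of named genes, 1071 kept direction and side of the threshold, 204 passed a threshold missed before and 3 turned. In the main edgeR fit no named gene passed over all genes, so keeping its side meant staying uncalled and no call could be lost. Some genes were named by the authors' adjusted p, which DESeq2 run here repeats, so their passing there is no separate support.

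For genes near regions the adjusted p of limma camera was 0.231 with an estimated correlation for the progenitor-only p63 and differentiated-only H3K27ac sets, and 0.0482 within 10 kb for the shared p63 and progenitor-only H3K27ac sets. Without 1 library it ran from 0.0097 to 0.465 for progenitor-only p63, 0.0224 to 0.914 for shared p63 and 0.00091 to 0.914 for differentiated-only H3K27ac. With equal numbers of peaks, which tend to balance the counts by construction, there were 2049 progenitor-only and 1980 differentiated-only p63 regions. When a peak had to cover 50% of the region there were 7232 progenitor-only p63 and 20019 shared H3K27ac regions. Without 1 library, progenitor-only and differentiated-only counts ran from 4871 to 12912 and 622 to 2031 for p63, and from 21385 to 34192 and 13816 to 19894 for H3K27ac, since fewer lists then have to hold or lack a peak. The p63 overlap with H3K27ac ran from 42.7% to 52.5% in progenitor and 36.4% to 40.3% in differentiated cells, and with the summit inside it was 22% and 20.5%. At single genes 851 region counts were equal to the main count or within 1.5 times of it. Another 109 moved further, counting any change to or from none. The motif search was not run, and the pseudocount alternatives did not apply to counts. Depth limits genes with few reads, and that of the ChIP libraries is unknown.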

Other observations

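In this part the test of a less differentiated culture was chosen only after the result was seen. Genes of the cytosolic ribosome had a median log2 difference of 0.34 over 63 members, and RPL32 and RPS24 at 0.43 (SE 0.32) and 0.51 (SE 0.37). Both CASZ1 siRNA libraries were above both controls in 43 members, where chance gives 10.5 for genes that vary independently. Ribosomal genes vary together over these 4 libraries, so the 2 counts do not make a test. Limma camera gave an adjusted p of 2.2e-10 with the preset correlation, and an adjusted p of 0.489 with an estimated correlation. By edgeR 0 members passed over all genes or adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 in the authors' deposited table. Notch pathway genes had a median of −0.99 over 14 members, with the receptor NOTCH2 at −1.78 (SE 0.57) and the repressor HES2 at −2.35 (SE 0.76), an adjusted p of 0.0051 by preset limma camera and an adjusted p of 0.489 with an estimated correlation, and the preset call ended without control A (adjusted p 0.154). By edgeR 0 of the 14 passed over all genes or adjusted over the list alone, with 3 lower and 0 higher at an unadjusted p under 0.05. The authors' deposited table called 0 over all genes, with DESeq2 adjusted p of 0.227 for NOTCH2 and 0.0933 for HES2, and 2 lower adjusted over the list alone. The Notch median was −0.29 without control A and −1.76 without control B, where 6 fell and 1 rose by edgeR adjusted over the list alone. Unfolded protein genes had a median of 0.45 over 30 members, with the chaperone HSP90B1 at 0.90 (SE 0.31), an adjusted p of 0.0057 by preset limma camera and an adjusted p of 0.489 with an estimated correlation, and the preset call ended without control B (0.486) and turned without CASZ1 siRNA A (0.865). Replication histone genes had a median of −0.46 over 9 members. Only these 9 of 32 could be tested in the poly(A) selected RNA, so the values do not cover the list as a whole. The histone list had an adjusted p of 0.039 by preset limma camera and an adjusted p of 0.489 with an estimated correlation. Its preset call ended without control B and without CASZ1 siRNA B. In both of these lists edgeR called 0 over all genes or adjusted over the list alone, and 0 were called in the authors' deposited table. At an unadjusted edgeR p under 0.05, 1 unfolded protein gene was higher and 1 histone gene lower. Adjusted over the list alone by edgeR, 1 unfolded protein gene rose without CASZ1 siRNA B and 1 histone gene fell without control B.

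Of wound response genes, the antimicrobial genes DEFB103A and RNASE7 fell and IL1B rose by edgeR adjusted over the list alone, 2 lower and 1 higher of 25, against 0 over all genes in edgeR (3 lower and 1 higher at an unadjusted p under 0.05) and 2 lower and 1 higher in the authors' deposited table. Adjusted over the list alone, the authors' deposited table gave 3 lower and 2 higher, and limma voom 1 and 1. RNASE7 was at 769 and 77.8 CPM in the controls and at 15.9 and 16.0 CPM with CASZ1 siRNA. By edgeR adjusted over the list alone, 0 of these genes rose without control A, 0 rose and 1 fell without CASZ1 siRNA A, and 3 rose without control B or CASZ1 siRNA B. Of 30 hypoxia genes edgeR called 0 over all genes or adjusted over the list alone, with 3 lower and 0 higher at an unadjusted p under 0.05, but 4 fell adjusted over the list alone without control B. Of this list the authors' deposited table called PFKFB3 (−3.44) and EGLN3 (−3.29) lower, and 3 genes lower adjusted over the list alone. Control A and B differed in both, at 111 and 9.86 CPM for PFKFB3 and at 32.0 and 2.36 CPM for EGLN3, against 5.56 and 5.23 CPM and 1.62 and 1.80 CPM with CASZ1 siRNA. The preset limma camera adjusted p was 0.483 for wound, 0.0515 for interferon, 0.494 for cholesterol synthesis, 0.598 for mesenchymal matrix, 0.726 for p53 targets, 0.190 for hypoxia, 0.267 for fibroblast and 0.544 for melanocyte lists. In the interferon, cholesterol, mesenchymal, p53, fibroblast and melanocyte lists edgeR called 0 over all genes or adjusted over the list alone. At an unadjusted edgeR p under 0.05, 1 interferon gene was higher, and 2 mesenchymal, 1 p53, 1 fibroblast and 1 melanocyte gene were lower. The authors' deposited table called none of these over all genes, and 1 p53 and 1 fibroblast gene lower adjusted over the list alone. By edgeR adjusted over the list alone, 1 mesenchymal and 2 melanocyte genes fell without control B, and 1 interferon and 1 fibroblast gene rose without CASZ1 siRNA B. For mesenchymal and p53 genes the median (0.094 and 0.048) and the mean (−0.049 and −0.080) differed in sign. Melanocyte genes differed between library A and B by a median of 2.33 in the controls and 2.23 with CASZ1 siRNA, and cholesterol synthesis genes by −1.56 and −0.69. The Langerhans and Merkel cell lists had 2 tested members each and no set test, and the mitochondrial list had 0 members in the table.

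Cornified envelope genes had a list median of −2.33 with CASZ1 siRNA. Variation of the kind seen between libraries of a group would keep it within the larger A to B median of 0.799, and it exceeded that by 1.53 (standard error of the median 0.654, over genes that vary together). The A to B median is of signed differences, so opposite ones cancel and it can understate the spread. In control A and B the LCE1 genes summed to 1685 and 106 CPM, while FLG stood at 32.0 and 209 CPM. It was also taken on log2 CPM with a prior count of 2, unlike the edgeR fold changes. Each group gives a single A to B difference, so larger variation between libraries is not excluded. Reads shared within the LCE and SPRR families would leave the rest near 0, but the median of the 24 other members was −1.29 (standard error 0.51), with 9 lower adjusted over the list alone by edgeR. The list median lay below that of the spinous layer list by −2.06 (95% bootstrap interval over genes −3.82 to −1.04), which a culture less far along in differentiation could also give, since it would lower late genes more than early ones. Larger variation between libraries, a less differentiated culture, a dependence of late differentiation genes on CASZ1 and an off-target effect of the siRNA all stay open, the last 2 untested.

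SPRR2A rose while the other 4 tested SPRR2 genes fell adjusted over the list alone by edgeR. Reads could have moved between these near-identical genes, and the gain of SPRR2A, 115 CPM, was 0.312 of the 369 CPM lost by the others, so that a move is possible. The family's sum, 515 CPM in the controls and 262 with CASZ1 siRNA, a ratio of 1.97, is not what a move alone would give. Moved reads and a separate rise of SPRR2A cannot be told apart from these counts.

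Fewer p63 regions were found in differentiated cells, and depth or enrichment could have set this. Of 4838 regions in the strongest 25% of both progenitor lists, 48 were missing from both differentiated lists, 0.992 percentage points above the 0% missing from a list's own replicate and just under the bound of 1 point set beforehand. In the opposite direction 2 of 3568 were missing. By the authors' fold, the progenitor-only regions had median percentiles of 23.1 and 45.9 in their lists, and the differentiated-only regions 28.1 and 30.05. Being under the bound, the 0.992 points fall on the side set beforehand for weaker differentiated libraries. Weaker differentiated libraries and a loss of p63 binding still cannot be told apart here, since the read depth is unknown and the value lies at the bound.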
